A study of Mus musculus with 20 samples.

How the data were processed

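Expression was measured in mouse subiculum pyramidal cells, in 12 bulk RNA-seq libraries and in single cells sorted into plates. Per the labels' protocols, fluorescent neurons were taken by manual sorting out of slices that had been microdissected. The 12 bulk libraries are 3 biological replicates of each of 4 populations named by projection target (NA, PFC, RSC and VHN). The labels do not spell out these abbreviations. NA, PFC and RSC are customary short forms for nucleus accumbens, prefrontal cortex and retrosplenial cortex, and VHN is kept as the label gives it. The labels list 8 single-cell samples of 1 description, whereas the count table names its wells by 4 plates (Q5 to Q8). The wells were therefore treated as 1 pooled sample with the plate as a technical unit.

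The bulk values come from a Cuffdiff read-group tracking table, per the file headers. Per the submitters' processing notes the genome build was mm9, and aligner, software versions and annotation release are not stated. The authors' raw fragment values are expected counts per gene and library, without normalization, per the file headers. Of the expected counts above 0, 8.51% were not whole, so all were rounded before count tests. The authors also deposited FPKM values, made with a size factor per library. The table counts replicates from 0 and the labels from 1. The same order was assumed only to name libraries, and the population of a library does not depend on it. The single-cell table holds whole-number counts per gene and well, as deposited, with no scaling. Whether molecular identifiers were used is not stated, so intervals and floors cover counting error only. No header or label states whether reads were counted by strand or how reads shared between gene copies were assigned. Values for overlapping, antisense or multicopy genes are uncertain for this reason.

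The bulk table held 37607 gene rows with Ensembl identifiers and 92 spike-in rows that were 0 in all 12 libraries and were left out. Symbols came from a later mouse annotation matched by identifier, which named 32894 gene rows (87.5%). No coordinates are given, since no mm9 annotation was at hand. Gene fragments per library ranged from 10777273 to 20904126. At least 1 fragment was present for 21114 genes, and 178 gene and library entries carried the status FAIL and were kept. The single-cell table held 47293 gene rows, of which 45342 matched a symbol. It covered 384 wells, of which 11 were empty.

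Bulk genes were filtered with filterByExpr of edgeR 4.0.16 at its default settings (smallest count 10), which left 13916 genes. Library sizes were scaled by TMM. All 12 libraries entered 1 quasi-likelihood fit, so that the 4 populations shared 1 estimate of the spread (common biological coefficient of variation 0.736, 8 residual degrees of freedom). Tests were the 4-group test, the 6 pairwise contrasts and the 3 ways to put 4 populations into 2 pairs. The Benjamini-Hochberg adjusted p threshold was 0.05, and a second count asked for an absolute log2 fold change of at least 1. Every adjusted p of a gene is from this edgeR test. A gene was set apart in 1 population when it passed all 3 pairwise tests of that population with the same sign. The size of the difference between each pair was the square root of the mean squared log2 difference after removal of noise, with a jackknife error over libraries. The noise came from the spread within groups pooled over the 4 populations. A value under 0 means that the difference did not exceed this pooled noise. Levels are CPM, which were computed here and scaled by TMM. Folds are ratios of arithmetic mean CPM. For pairs of populations, the edgeR log2 fold change averages the log levels of both, so it can differ from the log of that ratio.

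Gene lists of ion channels, receptors, transporters, neuropeptides, calcium-handling proteins, guidance and adhesion molecules, matrix proteins, transcription factors, immediate early and stress genes, genes reported to vary within subiculum, and markers of other cells and regions were written, with the tests, before the data were examined. Each list with at least 5 tested members was tested with camera of limma 3.58.1 on log2 CPM at the preset correlation, adjusted over 243 tests of 27 lists and 9 contrasts. No camera call held with an estimated correlation, against 46 at the preset value. Members were also adjusted over the list alone with the Benjamini-Hochberg method. The mean log2(CPM + 1) of marker and stress lists was compared among the 4 populations with a two-sided exact permutation F test over 15400 splits. The mitochondrially encoded genes had no fragment in any library, so their list had no test.

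Named genes follow a rule of the same date: per contrast, the 6 largest changes in each direction among genes with a symbol, an adjusted p under the threshold, at least 10 CPM on the higher side and no overlap between the libraries of the 2 sides, plus up to 4 members of each list with the lowest adjusted p. Members of the list of genes reported to vary within subiculum and of the marker lists are named where they matter. For genes set apart, the 6 with the largest smallest pairwise change per population were taken among those with at least 10 CPM on the higher side. For single-cell clusters, the 6 genes with the largest fold among genes seen in at least 25% of the cluster were taken. A fold against a group at 0 was computed against a floor of 3 fragments over the group, and is a lower bound. With 1 to 3 fragments, the ratio has a 95% counting interval.

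Single-cell wells with at least 1000 detected genes (348) were kept. No doublet caller was run. Counts were scaled to 10000 per cell and log2-transformed after adding 1. The 2000 most variable genes gave 20 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2). Shares of cells have exact binomial (Clopper-Pearson) 95% intervals. Cells are not replicates, and no p-value is given for them. For each bulk contrast with at least 10 called genes per side that were detected in at least 5% of pyramidal-like cells, the mean correlation across cells among genes of the same side minus that between opposite sides was computed. It was set beside 10000 random pairs of lists matched on mean expression in 20 bins.

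Both parts were tested on simulated data. In counts simulated with known changes between PFC and NA (13564 genes run, 3 libraries each, all 12 in the fit), the fit recovered 22% of genes changed 2-fold, 70% at 4-fold, 88% at 8-fold and 98% at 16-fold. The changed genes were drawn from those with a mean of at least 10 CPM, so recovery under that level was not measured. The fit called 4 unchanged genes in PFC against NA and 0 in NA against RSC, where none was changed. The segregation value of 100 against 100 genes across 348 simulated cells was 0.00197 with no difference between classes of cells and 0.0872 with a 2-fold difference (6000 genes run).

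Alternatives were DESeq2 1.42.0, RLE size factors, no normalization, no and stricter low-count filters, the replicate number as a block, limma on log2 FPKM with both pseudocounts, a threshold of 0.01, each library left out, the libraries of only the compared populations, fry in place of camera, and other cell filters, resolutions and measures for single cells. Sets of libraries that stood apart were also left out. Sequence searches used BLAST+ 2.17.0. Other tools were R 4.3.3, Python 3.11.15, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.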

Results

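Gene expression was compared among subiculum pyramidal cells that project to different targets, and the same cell type was then profiled cell by cell. The subiculum is the main output region of the hippocampal formation. The bulk part held 12 libraries, 3 for each of the populations labelled NA, PFC, RSC and VHN. Depth was 17031054, 11325173 and 18997292 gene fragments in NA replicates 1 to 3, and 10873160, 14019666 and 10777273 in those of PFC. It was 17399784, 18280512 and 20904126 in RSC and 18063655, 15747769 and 16210121 in VHN. The single-cell part held 384 wells on 4 plates of 96. Of these, 348 wells had at least 1000 detected genes, with a median of 112401 counts (2795 to 322542) and 5222 detected genes per cell.

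The first question was which of the 4 populations share expression. NA and PFC libraries lay on one side of the first principal component and RSC and VHN libraries on the other. Across the 13916 genes tested, 1243 differed among the populations (edgeR 4-group test, smallest adjusted p = 9.73e-06). The noise-corrected log2 difference was 1.10 (jackknife SE 0.167) between NA and RSC, 0.93 (SE 0.266) between NA and VHN, 1.28 (SE 0.053) between PFC and RSC and 1.05 (SE 0.088) between PFC and VHN. Within these sides it was 0.66 (SE 0.284) between NA and PFC and −0.19 (SE 0.575) between RSC and VHN, each from 3 libraries per population. The last value turned positive without some single libraries, up to 0.33 without NA replicate 2, a library of neither population. It was also positive without NA replicate 2 and PFC replicate 3 together. Its noise is pooled over all populations, so a value under 0 does not show that RSC and VHN are alike. NA replicate 2 stood apart on the second component and PFC replicate 3 on the third, which carried 11.6% of the variance.

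**Figure D1:**
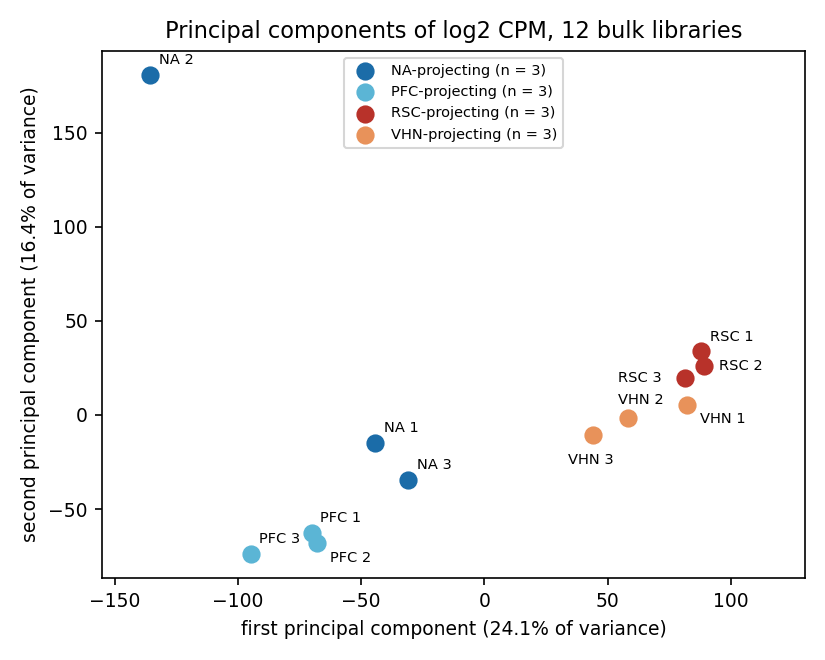
First and second principal component scores (arbitrary units) of log2 CPM for the 12 bulk libraries, 1 point per library, coloured by projection target with 3 libraries each. The first component, with 24.1% of the variance, has all NA and PFC libraries below 0 and all RSC and VHN libraries above 0.

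NA and PFC cells together differed from RSC and VHN cells together in 1982 genes, 1055 higher and 927 lower (913 and 1046 without normalization). The extracellular matrix protein fibronectin, Fn1 (ENSMUSG00000026193), was at 499 ± 133 CPM in RSC and VHN and 2.74 ± 5.78 CPM in NA and PFC (SD, n = 6 each). These means differed 182-fold. The log2 fold change was larger (−10.13, SE 0.854, edgeR adjusted p = 2.12e-06), since it averages the log levels of the populations. The 2 measures differ in this way for all genes of this contrast. NA replicate 3, at 14.45 CPM, carried most of the NA and PFC mean, so the fold depends on it. The receptor tyrosine kinase Kit (ENSMUSG00000005672) went the other way, at 266 ± 75.8 CPM in NA and PFC and 6.58 ± 9.54 CPM in RSC and VHN (SD, n = 6 each), 40.4-fold (log2 fold change 6.62, SE 0.680, edgeR adjusted p = 1.05e-05). VHN replicates 2 and 3, at 15.7 and 21.6 CPM, carried most of the RSC and VHN mean of Kit. The neuropeptide neurotensin, Nts (ENSMUSG00000019890), was at 332 ± 62.6 CPM in RSC and 293 ± 105 CPM in VHN, against 21.3 ± 3.72 CPM in NA and 18.8 ± 11.2 CPM in PFC (SD, n = 3 each; log2 fold change −3.96, edgeR adjusted p = 8.32e-07). By the naming rule, no library of one side overlapped the other for Fn1, Kit or the genes named next.

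Further genes were far higher in NA and PFC. The transcription factor gene Zfhx4 (32.9 ± 35.7 CPM) was 109-fold higher, Piga, needed to make GPI anchors, 160-fold and Mei4 (33.4 ± 56.6 CPM) 185-fold. The opioid peptide precursor Penk (10.2 ± 14.5 CPM) was at least 371-fold higher, since RSC and VHN held 0 fragments of it. PFC carried it, at 19.4 ± 16.5 CPM against 1.02 ± 0.478 CPM in NA (SD, n = 3 each). The ratio for the transcription factor St18 (20.6 ± 34.1 CPM) was 2350 (counting interval 353 to 77600), with 1 fragment in RSC and VHN. For Zfhx4, Mei4, Penk and St18 the SD of the pooled mean (n = 6 each) exceeded the mean, so libraries differed widely. Piga was at 13.2 ± 6.47 CPM (SD, n = 6). Higher in RSC and VHN were the matrix protein thrombospondin 1, Thbs1 (423-fold), Slc35d3 (226-fold) and Whrn (168-fold). The ratio there was 1400 (counting interval 217 to 47800) for Lipm and 424 (154 to 2180) for Mctp2. Of the genes of the pairwise contrasts, 159 were higher and 166 lower both in NA against RSC and in PFC against VHN, which share no library. Independent lists would share 11.7 and 8.8, and 0 genes moved in opposite directions. NA against VHN and PFC against RSC, also without a common library, shared 139 higher and 118 lower genes (11 and 7.7 expected), and 1 moved in opposite directions. These expected counts take every gene as equally likely to be called. Since 1 fit gave all contrasts a shared spread per gene, the excess over them may be overstated.

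**Figure D2:**
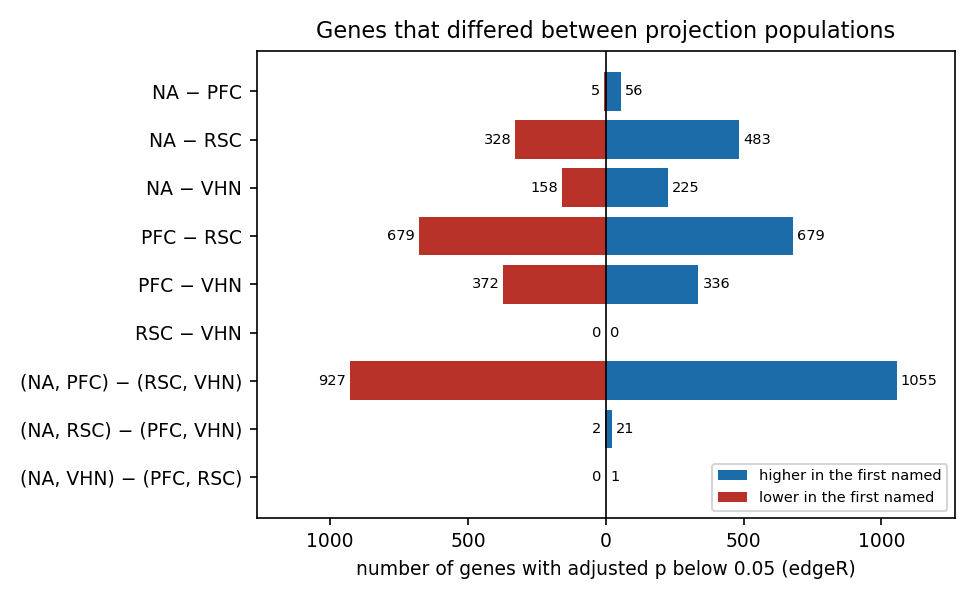
Number of genes with an edgeR adjusted p under 0.05 in each contrast, as bars from 0 to the right for genes higher and to the left for genes lower in the population or pair named first. The bars of NA and PFC against RSC and VHN reach 1055 and 927, those of RSC against VHN are at 0.

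Ion channel genes of both sides were among them. Of 48 voltage-gated potassium channel genes tested, 11 were higher in NA and PFC and 10 lower. The A-type channel genes Kcnd2 (log2 fold change 1.18, edgeR adjusted p = 0.000395) and Kcnd3 (2.89, adjusted p = 0.000357) were higher. The auxiliary subunit Kcnab3 (−3.73, adjusted p = 1.66e-05) and Kcna5 (−8.29, adjusted p = 0.000537) were lower. Adjusted over the list alone, 23 passed, and the list as a whole had camera adjusted p = 0.196. Of 24 sodium, HCN and related channel genes, 4 were higher and 3 lower (9 adjusted over the list alone, camera adjusted p = 0.952). The sodium channel subunit Scn4b changed most clearly (−3.34, edgeR adjusted p = 2.37e-05). Of 13 inward-rectifier and two-pore channels, 2 were higher and 1 lower (3 adjusted over the list alone, camera adjusted p = 0.493). Of 20 calcium channel genes, 7 were higher and 1 lower, with 12 adjusted over the list alone. The subunit Cacna2d1, a target of gabapentin, led them (2.39, edgeR adjusted p = 8.32e-07), with Cacna1e (1.64, adjusted p = 4.53e-06) and Cacnb2 (2.14, adjusted p = 0.000185). As a list, calcium channels were called toward NA and PFC (camera adjusted p = 0.0224, but adjusted p = 0.144 with an estimated correlation).

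Of the transmitter receptor and transporter genes, 27 of 80 tested were called higher in NA and PFC and 7 lower, and the rest did not pass. Of 23 glutamate receptor genes, 8 were higher and 2 lower (14 adjusted over the list alone), among them the kainate receptor Grik4 (6.57, edgeR adjusted p = 0.000205) and the NMDA receptor Grin2b (0.83, adjusted p = 0.000143). Their camera adjusted p = 0.0233 became adjusted p = 0.144 with an estimated correlation. Of 17 GABA and glycine receptor genes, 4 were higher and Gabrd (−3.05, edgeR adjusted p = 0.00615) was lower. These were 8 adjusted over the list alone, with camera adjusted p = 0.0371 and adjusted p = 0.327 with an estimated correlation. Of 31 monoamine, acetylcholine, adenosine and cannabinoid receptor genes, 11 were higher and 3 lower (21 adjusted over the list alone, camera adjusted p = 0.1). The serotonin receptor Htr2c was at 81.1 ± 42.4 CPM in NA and 178 ± 37.2 CPM in PFC, against 2.15 ± 0.379 CPM in RSC and 20.8 ± 13.4 CPM in VHN (SD, n = 3 each; log2 fold change over the pairs 4.17, edgeR adjusted p = 7.06e-06). The muscarinic receptor Chrm1 was also higher (1.03, adjusted p = 9.45e-05). Of 9 transporter genes, 4 were higher and 1 lower (8 adjusted over the list alone, camera adjusted p = 0.120). The vesicular glutamate transporters went apart, Slc17a7 higher (0.61, edgeR adjusted p = 0.000759) and Slc17a6 lower (−2.01, adjusted p = 7.95e-06).

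Of 18 neuropeptide and secreted signal genes, 4 were higher and 3 lower (11 adjusted over the list alone, camera adjusted p = 0.551). Besides Penk, the neuregulin Nrg3 (1.14, edgeR adjusted p = 0.0012) was higher in NA and PFC, and Nts was lower. Of 23 neuropeptide receptor genes, 3 were higher and 3 lower (8 adjusted over the list alone), with Gpr12 at 4.78 (edgeR adjusted p = 0.000201) and Gpr101 at −3.89 (adjusted p = 5.86e-05). Their camera adjusted p = 0.812, with a median of −0.27 and a mean of 0.23. Of 29 calcium-binding and calcium-signalling genes, 10 were higher and 2 lower (20 adjusted over the list alone). Hpcal4 (1.85, edgeR adjusted p = 2.34e-06), Calb1, encoding calbindin (4.88, adjusted p = 0.00134), and the kinase gene Camk2a (0.72, adjusted p = 0.000546) were higher. The list had camera adjusted p = 0.0172 and adjusted p = 0.241 with an estimated correlation.

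**Figure D3:**
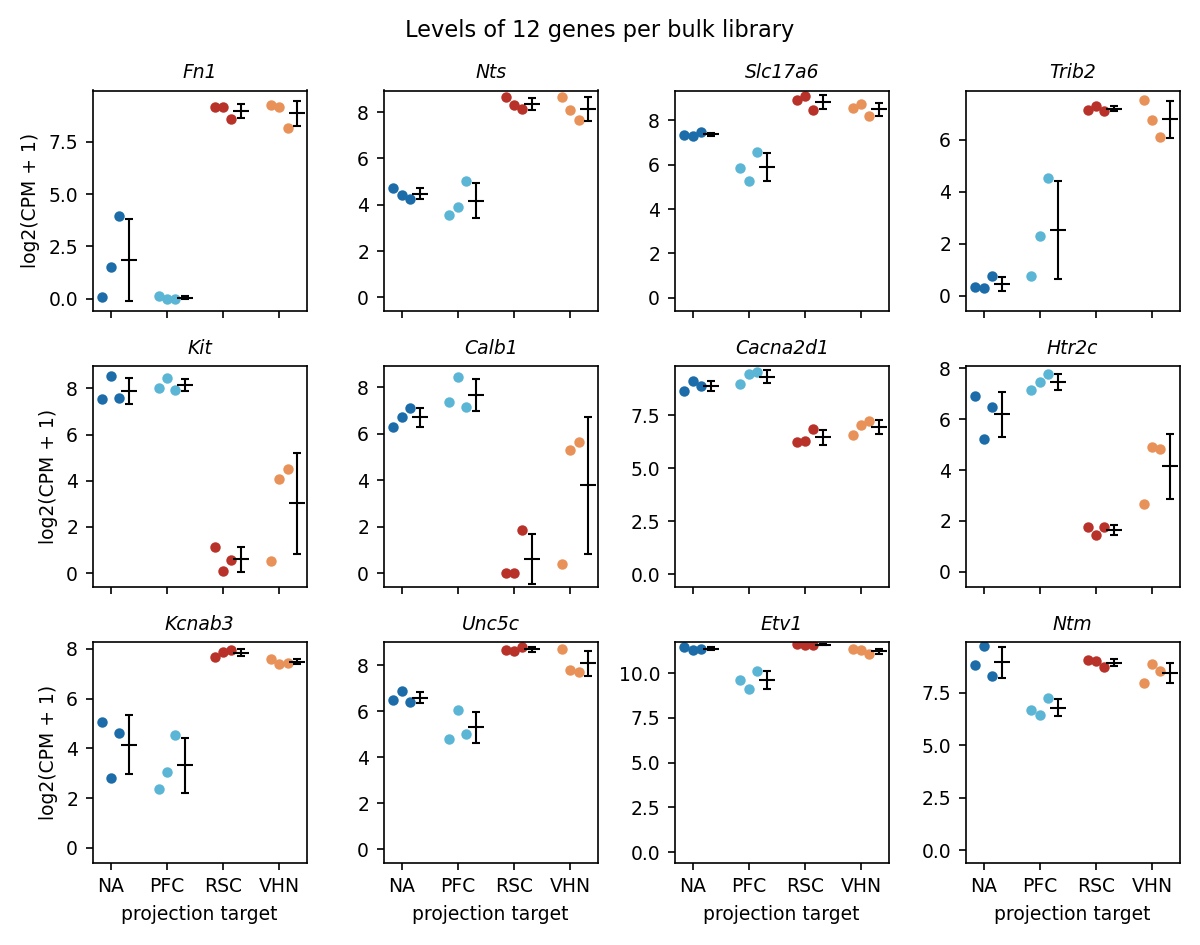
Levels of 12 genes as log2(CPM + 1), 1 point per bulk library with 3 libraries per projection target, and beside them the mean with bars of 1 SD. Fn1, Nts and Trib2 were higher in RSC and VHN, Kit, Cacna2d1 and Htr2c higher in NA and PFC, and Etv1 and Ntm lower in PFC than in NA.

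Adhesion, guidance and matrix genes, which shape connections, were also tested. Of 46 synaptic adhesion genes, 18 were higher in NA and PFC and 7 lower (33 adjusted over the list alone), such as Cadm1 (1.40, edgeR adjusted p = 1.38e-05) and the teneurin Tenm3 (−1.81, adjusted p = 2.42e-05). Their camera adjusted p = 0.0236 became adjusted p = 0.144 with an estimated correlation. Of 25 cadherins and protocadherins, 9 were higher and 5 lower (16 adjusted over the list alone, camera adjusted p = 0.0763), with Pcdh20 at 5.55 (edgeR adjusted p = 3.4e-05) and Cdh7 at −3.17 (adjusted p = 4.05e-05). Of 58 axon guidance genes, 12 were higher and 5 lower (22 adjusted over the list alone). The netrin receptor Unc5c was at −2.44 (edgeR adjusted p = 6.81e-06) and the ligand Slit1 at 2.95 (adjusted p = 5.28e-05). Their camera adjusted p = 0.0366 became adjusted p = 0.144 with an estimated correlation. Of 31 extracellular matrix genes, 11 were higher and 4 lower (15 adjusted over the list alone). Nell2 was higher (1.62, edgeR adjusted p = 3.79e-06), and Sparcl1 (−1.85, adjusted p = 3.35e-06), Fn1 and Thbs1 lower. The list had camera adjusted p = 0.0476 and adjusted p = 0.253 with an estimated correlation.

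Of 60 transcription factor genes, 16 were higher and 8 lower in NA and PFC (28 adjusted over the list alone). Lmo4 (1.43, edgeR adjusted p = 4.49e-05), Neurod6 (1.83, adjusted p = 0.000108) and Lhx2 (6.10, adjusted p = 0.000217) were higher. Etv1 (−0.89, adjusted p = 0.00016) was lower, at 812 CPM in PFC, whereas NA (2625 CPM) lay between VHN (2380 CPM) and RSC (3081 CPM). Their camera adjusted p = 0.0371 became adjusted p = 0.220 with an estimated correlation. Of 12 excitatory pyramidal markers, 6 were higher and Slc17a6 lower (9 adjusted over the list alone, camera adjusted p = 0.0224 and adjusted p = 0.183 with an estimated correlation). Of 18 genes reported to vary within subiculum, 5 were higher and 5 lower (13 adjusted over the list alone). Its camera adjusted p = 0.872. Besides Fn1, Nts, Gpr101 and Slc17a6, it holds Dlk1 (8.01, edgeR adjusted p = 0.00133), Col5a2 (6.23, adjusted p = 0.000943) and Ntng2 (3.62, adjusted p = 0.0002), all higher in NA and PFC. Because such reports may have drawn on cells of this region, these members are not independent evidence of a direction.

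Of 4 marker lists of neighbouring regions, the CA1 list alone passed at the preset correlation. Of 11 CA1 pyramidal markers, 5 were higher in NA and PFC and Mpped1 (−0.69, edgeR adjusted p = 0.0137) lower, 8 adjusted over the list alone. Zbtb20 (3.86, edgeR adjusted p = 0.000529) and Man1a (1.86, adjusted p = 1.98e-05) were among the higher ones. The list had camera adjusted p = 0.00767 and adjusted p = 0.205 with an estimated correlation. Its mean level was 6.09 ± 0.0599 in NA, 6.80 ± 0.633 in PFC, 5.34 ± 0.117 in RSC and 5.33 ± 0.214 in VHN (log2(CPM + 1), SD, n = 3 each), exact permutation F test p = 0.00201, adjusted 0.0131. Of 13 CA3 and CA2 markers, 3 were higher and Prkcd (−4.30, edgeR adjusted p = 0.0121) lower (6 adjusted over the list alone, camera adjusted p = 0.166, exact permutation F test p = 0.0234, adjusted 0.0760). Of 8 dentate granule markers, Calb1 was higher and C1ql3 lower (−1.96, edgeR adjusted p = 0.000262), with 2 adjusted over the list alone, camera adjusted p = 0.435 and exact permutation F test p = 0.0315, adjusted 0.0819. Of 12 presubiculum, entorhinal and deep neocortical markers, 2 were higher and 2 lower (5 adjusted over the list alone, camera adjusted p = 0.715, exact permutation F test p = 0.236, adjusted 0.352). Crym (−1.57, edgeR adjusted p = 0.000233) was lower.

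Immediate early genes, which follow neuronal activity, were higher in NA and PFC as a mean level. It was 4.45 ± 0.055 in NA, 4.69 ± 0.192 in PFC, 3.83 ± 0.106 in RSC and 4.08 ± 0.227 in VHN (log2(CPM + 1), SD, n = 3 each), exact permutation F test p = 0.00026, adjusted 0.00338. Of 22 tested members, 6 were higher and 2 lower (9 adjusted over the list alone, camera adjusted p = 0.0371 and adjusted p = 0.205 with an estimated correlation), with Nr4a3 at 2.55 (edgeR adjusted p = 0.00207) and Ier5 at −1.52 (adjusted p = 1.69e-05). Of 19 heat shock and stress genes, 5 were lower and Hmox1 (5.91, edgeR adjusted p = 0.0158) higher (6 adjusted over the list alone, camera adjusted p = 0.0359 and adjusted p = 0.198 with an estimated correlation). Their median was −0.41 and their mean 0.04, and their level had exact permutation F test p = 0.0427, adjusted 0.0924.

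Transcripts of other cell types were also measured. All 4 called interneuron markers of the 10 tested were lower in NA and PFC, Gad1 (−6.70, adjusted p just under 0.05), Gad2 (−5.03, edgeR adjusted p = 0.0312), Pvalb (−4.83, adjusted p = 0.0129) and Npy (−6.35, adjusted p = 0.0313). Adjusted over the list alone, 5 passed, and camera gave adjusted p = 0.308. Gad2 was at 43.3 and 177 CPM in RSC replicates 2 and 3 and 91.9 CPM in VHN replicate 3, and at 0, 0.158 and 0.238 CPM in the other 3 libraries of these populations. Without those 3 libraries, 746 genes differed, and the log2 fold changes of Gad1 and Gad2 turned to 3.41 and 5.15 (edgeR adjusted p = 1 and 0.234). Of 6 astrocyte markers, Slc1a2 was higher (1.10, edgeR adjusted p = 0.01; 2 adjusted over the list alone, camera adjusted p = 0.314). Of 5 oligodendrocyte markers, 1 was lower (edgeR; 1 adjusted over the list alone, camera adjusted p = 0.707). Of 3 endothelial and mural markers, Rgs5 was higher (2.76, edgeR adjusted p = 0.00339; 1 adjusted over the list alone). None of the 2 microglia markers and 4 sex-linked transcripts tested passed (edgeR; 0 adjusted over the list alone), and no oligodendrocyte precursor marker was abundant enough for a test. In the exact permutation F test of list levels, oligodendrocyte markers passed (p = 0.00851, adjusted 0.0369; levels are given with RSC and VHN). For the other lists p was 0.427 for interneuron, 0.0555 for astrocyte, 0.415 for oligodendrocyte precursor, 0.839 for microglia, 0.252 for endothelial markers and 0.271 for sex-linked transcripts (adjusted 0.462, 0.103, 0.462, 0.839, 0.352 and 0.352).

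The transcript with the highest level of all that moved with this contrast, named here after its values were seen, was Lars2, the mitochondrial leucyl-tRNA synthetase. It was at 14020 ± 2935 CPM in NA and 9538 ± 2663 in PFC, against 1079 ± 295 in RSC and 1925 ± 898 in VHN (SD, n = 3 each; log2 fold change 3.00, edgeR adjusted p = 8.32e-07). The RNA component of ribonuclease P, Rpph1, also chosen after its values were seen, was at 16.5 ± 2.46 and 19.3 ± 12.7 CPM in NA and PFC and 1.87 ± 1.17 and 2.10 ± 1.60 CPM in RSC and VHN (SD, n = 3 each; log2 fold change 3.17, edgeR adjusted p = 0.00298).

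NA and PFC cells differed from each other in 61 genes, 56 higher in NA and 5 higher in PFC. In PFC, the potassium channel subunit Kcnab1 (ENSMUSG00000027827) was at 96.5 ± 44.2 CPM, against 7.63 ± 6.02 CPM in NA (SD, n = 3 each; 12.6-fold, log2 fold change −3.65, SE 0.613, edgeR adjusted p = 0.0129). The copine gene Cpne6 was 2.73-fold and the synapsin Syn2 2.45-fold higher in PFC. Rps15, a ribosomal protein gene whose reads processed copies may share, was 3.06-fold higher. In NA, the adhesion molecule neurotrimin, Ntm (ENSMUSG00000059974), was at 543 ± 284 CPM, against 114 ± 33.8 CPM in PFC (SD, n = 3 each; 4.79-fold, log2 fold change 2.26, SE 0.330, edgeR adjusted p = 0.00684). Asah2, a neutral ceramidase (108 ± 124 CPM), was 12.7-fold, Osbpl3 (81.7 ± 82.5 CPM) 8.08-fold, Pcsk5 (38.2 ± 26.1 CPM; SD, n = 3 each) 6.46-fold, Tnfaip8l3 3.88-fold and Elfn1 3.75-fold higher in NA. The transcription factor Etv1 had the lowest adjusted p, at 2625 ± 169 CPM in NA and 812 ± 271 CPM in PFC (SD, n = 3 each; log2 fold change 1.69, SE 0.180, edgeR adjusted p = 0.000631).

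Members of the fixed lists that differed between NA and PFC were few. Besides Kcnab1, Ntm and Etv1, they included Kcnf1 (1.76, edgeR adjusted p = 0.0202), Cacna1h (1.49, adjusted p = 0.0461), Slc17a6 (1.38, adjusted p = 0.0383), Adgra1 (1.67, adjusted p = 0.000768), Cntnap5a (1.34, adjusted p = 0.0316), Ldb2 (1.21, adjusted p = 0.00684), Fosl2 (1.21, adjusted p = 0.0342), Ier5 (1.22, adjusted p = 0.0316) and Atf4 (1.78, adjusted p = 0.0461), all higher in NA. Synaptic adhesion genes were called toward NA as a list (7 of 46 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0317 and adjusted p = 0.144 with an estimated correlation). So were stress genes (6 of 19 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0247 and adjusted p = 0.186 with an estimated correlation) and genes reported to vary within subiculum (4 of 18 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0236 and adjusted p = 0.144 with an estimated correlation). The count of 61 was 152 without NA replicate 3, 37 without NA replicate 2, 22 without PFC replicate 2, 29 without PFC replicate 3, 36 without each RSC replicate in turn and 34 without VHN replicate 2. It was 0 with the 6 libraries of these populations alone, and 464 by DESeq2.

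The 4 contrasts across the sides gave the largest pairwise counts. NA differed from RSC in 811 genes, 483 higher and 328 lower (407 and 405 without normalization). Dlk1, a Notch-related ligand, was at 133 ± 145 CPM in NA (SD, n = 3) and 0 fragments in RSC, at least 2490-fold higher. Cadherin 4, Cdh4 (ENSMUSG00000000305), was at 48.9 ± 17.7 CPM in NA (SD, n = 3), and its ratio to the 1 fragment in RSC was 3040 (counting interval 476 to 105000; edgeR adjusted p = 0.000986). Higher in NA with a wide spread and 0 fragments in RSC were Sox9 (20.6 ± 34.8 CPM, at least 386-fold), Plekha2 (18.2 ± 27.3, at least 342-fold), St6gal1 (12.3 ± 10.5, at least 230-fold) and the gene model Gm17035 (12.2 ± 14.6, at least 229-fold; SD, n = 3 each). In RSC, the pseudokinase Trib2 (ENSMUSG00000020601) was at 145 ± 9.95 CPM, against 0.380 ± 0.258 CPM in NA (SD, n = 3 each; 380-fold, edgeR adjusted p = 0.000274). Thbs1 was 361-fold higher, Slc35d3 at least 179-fold and Skint1 at least 160-fold, and the ratio was 602 (counting interval 207 to 6180) for Whrn and 629 (108 to 23800) for Lipm. Of the lists, calcium channels (5 of 20 higher and 2 lower, 9 and 2 adjusted over the list alone) and synaptic adhesion genes (10 of 46 higher and 4 lower, 17 and 5 adjusted over the list alone) were called toward NA. Both had camera adjusted p = 0.00767 and adjusted p = 0.144 with an estimated correlation. Also called toward NA were axon guidance genes (10 of 58 higher and 3 lower, 15 and 4 adjusted over the list alone, camera adjusted p = 0.0149 and adjusted p = 0.144 with an estimated correlation), immediate early genes (2 of 22 higher and 1 lower, 4 and 1 adjusted over the list alone, camera adjusted p = 0.0328 and adjusted p = 0.198 with an estimated correlation) and glutamate receptors (4 of 23 higher and 1 lower, 7 and 2 adjusted over the list alone, camera adjusted p = 0.0359 and adjusted p = 0.172 with an estimated correlation). The same direction was called for transcription factors (8 of 60 higher and 1 lower, 11 and 6 adjusted over the list alone, camera adjusted p = 0.0371 and adjusted p = 0.220 with an estimated correlation) and CA1 markers (2 of 11 higher and 0 lower, 3 and 1 adjusted over the list alone, camera adjusted p = 0.0476 and adjusted p = 0.290 with an estimated correlation). The count was 425, 387 and 472 without RSC replicates 1, 2 and 3, 110 without the 3 libraries richest in interneuron transcripts and 1654 by DESeq2.

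NA differed from VHN in 383 genes, 225 higher and 158 lower, a majority that turned without normalization (135 and 264). Kit was at 249 ± 103 CPM in NA and 12.6 ± 10.9 CPM in VHN (SD, n = 3 each; 19.8-fold, edgeR adjusted p = 0.0103). Higher in NA were also Myd88 (at least 206-fold), Mei4 (51.0 ± 83.3 CPM, 196-fold), Piga (61.9-fold), the catalase gene Cat (57.8 ± 86.0 CPM, 52.3-fold) and Slc30a10 (39.1 ± 42.3 CPM, 21.2-fold; SD, n = 3 each). Trib2 was at 119 ± 58.9 CPM in VHN (SD, n = 3), 313-fold above NA (edgeR adjusted p = 0.000601). Thbs1 was 157-fold and Slc35d3 at least 210-fold higher in VHN, and the ratio was 771 (counting interval 131 to 28800) for Lipm, 348 (124 to 3690) for Whrn and 194 (77 to 1090) for Mctp2. Synaptic adhesion genes were again called toward NA (10 of 46 higher and 2 lower, 19 and 7 adjusted over the list alone, camera adjusted p = 0.00456 and adjusted p = 0.144 with an estimated correlation). Other lists called toward NA were calcium channels (4 of 20 higher and 1 lower, 5 and 2 adjusted over the list alone, camera adjusted p = 0.0079 and adjusted p = 0.144 with an estimated correlation), CA1 markers (2 of 11 higher and 0 lower, 2 and 0 adjusted over the list alone, camera adjusted p = 0.0172 and adjusted p = 0.231 with an estimated correlation), calcium-binding and calcium-signalling genes (3 of 29 higher and 0 lower, 8 and 1 adjusted over the list alone, camera adjusted p = 0.0172 and adjusted p = 0.242 with an estimated correlation) and axon guidance genes (4 of 58 higher and 1 lower, 11 and 2 adjusted over the list alone, camera adjusted p = 0.0224 and adjusted p = 0.144 with an estimated correlation). Further ones were GABA and glycine receptors (2 of 17 higher and 0 lower, 5 and 0 adjusted over the list alone, camera adjusted p = 0.0318 and adjusted p = 0.309 with an estimated correlation), transcription factors (5 of 60 higher and 0 lower, 11 and 4 adjusted over the list alone, camera adjusted p = 0.0328 and adjusted p = 0.205 with an estimated correlation), excitatory pyramidal markers (3 of 12 higher and 1 lower, 4 and 1 adjusted over the list alone, camera adjusted p = 0.0328 and adjusted p = 0.198 with an estimated correlation) and glutamate receptors (2 of 23 higher and 0 lower, 6 and 2 adjusted over the list alone, camera adjusted p = 0.0345 and adjusted p = 0.166 with an estimated correlation). The count was 136, 156 and 248 without VHN replicates 1, 2 and 3, 183 without the 3 libraries richest in interneuron transcripts, 171 with the 6 libraries compared alone and 1077 by DESeq2.

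PFC differed from RSC in 1358 genes, 679 higher and 679 lower. Fn1 was at 507 ± 109 CPM in RSC (SD, n = 3), and its ratio to the 1 fragment in PFC was 17500 (counting interval 3290 to 724000; edgeR adjusted p = 2.25e-05). Mctp2 (at least 217-fold), the gene model Gm12198 (at least 192-fold), Lipm (at least 159-fold), the troponin gene Tnnt2 (at least 142-fold) and Skint1 (at least 131-fold) were higher in RSC. Zfhx4 was at 54.7 ± 41.9 CPM in PFC (SD, n = 3) and 0 fragments in RSC, at least 1020-fold higher (edgeR adjusted p = 0.000159). St18 (33.0 ± 48.6 CPM, at least 618-fold), Tmcc3 (at least 474-fold), Penk (at least 363-fold), the serotonin receptor Htr5b (18.8 ± 20.5 CPM, at least 353-fold) and Piga (at least 303-fold) were higher in PFC (SD, n = 3 each). Stress genes were called away from PFC (1 of 19 higher and 6 lower, 1 and 8 adjusted over the list alone, camera adjusted p = 0.00767 and adjusted p = 0.144 with an estimated correlation), with a median of −0.67 and a mean of 0.10. Called toward PFC were CA1 markers (5 of 11 higher and 0 lower, 7 and 1 adjusted over the list alone, camera adjusted p = 0.0154 and adjusted p = 0.220 with an estimated correlation), calcium-binding and calcium-signalling genes (9 of 29 higher and 3 lower, 14 and 3 adjusted over the list alone, camera adjusted p = 0.0359 and adjusted p = 0.280 with an estimated correlation) and excitatory pyramidal markers (6 of 12 higher and 1 lower, 7 and 1 adjusted over the list alone, camera adjusted p = 0.0476 and adjusted p = 0.205 with an estimated correlation). The count was 786, 744 and 875 without RSC replicates 1, 2 and 3, 214 without the 3 libraries richest in interneuron transcripts and 2128 by DESeq2.

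PFC differed from VHN in 708 genes, 336 higher and 372 lower. Fn1 was at 492 ± 180 CPM in VHN (SD, n = 3), with a ratio to PFC of 17000 (counting interval 3260 to 717000; edgeR adjusted p = 0.000107). Lipm (at least 195-fold), Mctp2 (at least 183-fold) and Gm12198 (at least 134-fold) were higher in VHN, and the ratio was 696 (counting interval 136 to 29900) for Thbs1 and 531 (81.3 to 17900) for the adrenergic receptor Adra1b. Penk (at least 342-fold) and Tex15 (15.3 ± 23.4 CPM, SD, n = 3, at least 269-fold) were higher in PFC. There the ratio was 1890 (counting interval 284 to 62500) for St18, 1390 (418 to 12500) for the calcium channel gene Orai2, 1130 (178 to 39100) for the dopamine receptor Drd1 and 956 (163 to 35900) for the gene model Gm23583. All 7 called CA1 markers of 11 were higher in PFC (7 adjusted over the list alone, camera adjusted p = 0.00456 and adjusted p = 0.187 with an estimated correlation). Also called toward PFC were calcium-binding and calcium-signalling genes (7 of 29 higher and 0 lower, 10 and 2 adjusted over the list alone, camera adjusted p = 0.00767 and adjusted p = 0.205 with an estimated correlation), GABA and glycine receptors (1 of 17 higher and 1 lower, 3 and 1 adjusted over the list alone, camera adjusted p = 0.0224 and adjusted p = 0.279 with an estimated correlation) and excitatory pyramidal markers (5 of 12 higher and 1 lower, 6 and 2 adjusted over the list alone, camera adjusted p = 0.0348 and adjusted p = 0.198 with an estimated correlation), and away from it stress genes (0 of 19 higher and 2 lower, 0 and 5 adjusted over the list alone, camera adjusted p = 0.0214 and adjusted p = 0.166 with an estimated correlation). The count was 1104 without NA replicate 2, 393 without PFC replicate 2, 358, 330 and 432 without VHN replicates 1, 2 and 3, 298 without the 3 libraries richest in interneuron transcripts and 1388 by DESeq2.

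RSC and VHN cells were not told apart by single genes in the fit used here. No gene passed (edgeR, smallest adjusted p = 0.219), with 721 at an unadjusted p under 0.05, 59 called by DESeq2 and 93 by edgeR without a low-count filter. Nts, Fn1 and Slc17a6 had similar means, at 332 and 293, 507 and 492, and 457 and 362 CPM in RSC and VHN. Others had unequal means but did not pass, such as Htr2c (2.15 ± 0.379 and 20.8 ± 13.4 CPM, edgeR adjusted p = 0.219), Kit (0.583 ± 0.585 and 12.6 ± 10.9, adjusted p = 0.219) and Calb1 (0.886 ± 1.53 and 29.2 ± 25.7, adjusted p = 0.544; SD, n = 3 each). Oligodendrocyte markers were called toward VHN as a list (0 of 5 called, 1 adjusted over the list alone, camera adjusted p = 0.00767 and adjusted p = 0.144 with an estimated correlation). Their mean level was 1.87 ± 0.654 in VHN and 0.896 ± 0.246 in RSC (log2(CPM + 1), SD, n = 3 each), exact permutation F test over the 4 populations p = 0.00851, adjusted 0.0369. That call was lost with log2(CPM + 0.1) (adjusted 0.102) and log2(FPKM + 1) (adjusted 0.0532). Without VHN replicate 1, 19 genes passed.

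The other ways to pair the populations gave few genes. NA and RSC together differed from PFC and VHN together in 23 genes, 21 higher and 2 lower. Asah2 was at 77.0 ± 85.6 and 15.5 ± 8.50 CPM (SD, n = 6 each; 4.96-fold, edgeR adjusted p = 0.0455), and the tubulin Tubb4a was 1.56-fold and Pura 1.48-fold higher. List members called included Etv1 (1.03, edgeR adjusted p = 0.00389), Ntm (1.35, adjusted p = 0.0395), Adgra1 (0.74, adjusted p = 0.0402) and, in the other direction, Htr2c (−2.20, adjusted p = 0.0402). NA and VHN together differed from PFC and RSC together in 1 gene, the adhesion receptor Adgra1 (0.93, edgeR adjusted p = 0.0286). Stress genes had a call toward NA and RSC (0 of 19 called, 4 adjusted over the list alone, camera adjusted p = 0.0154 and adjusted p = 0.144 with an estimated correlation), with a median of 0.25 and a mean of −0.05. Genes reported to vary within subiculum were called toward NA and VHN as a list (0 of 18 called, 6 adjusted over the list alone, camera adjusted p = 0.00328 and adjusted p = 0.144 with an estimated correlation). The same direction was called for oligodendrocyte markers (0 of 5 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.00767 and adjusted p = 0.144 with an estimated correlation), neuropeptide receptors (1 of 23 higher and 0 lower, 1 and 0 adjusted over the list alone, camera adjusted p = 0.0233 and adjusted p = 0.144 with an estimated correlation) and synaptic adhesion genes (0 of 46 higher and 0 lower, 4 and 2 adjusted over the list alone, camera adjusted p = 0.0291 and adjusted p = 0.144 with an estimated correlation). The 23 genes became 10, 13 and 51 without NA replicates 1, 2 and 3, 10 without PFC replicate 2, 3, 2 and 7 without RSC replicates 1, 2 and 3, and 3 each without VHN replicates 2 and 3. The single gene, Adgra1, became 0 genes without NA replicate 1, PFC replicate 2, RSC replicates 1 and 3 or VHN replicates 2 and 3, and 3, 3 and 11 genes without NA replicate 3, PFC replicate 3 and VHN replicate 1. Without RSC replicate 2, a gene other than Adgra1 passed.

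Genes set apart in 1 population numbered 45, of which 36 were lower and 2 higher in PFC and 5 higher and 2 lower in NA. RSC and VHN had 0 each (edgeR; since no gene separated them, none could be set apart). Lower in PFC than in each other population were Elfn1 (12.6 ± 10.6 CPM, n = 3, against 245 ± 176 CPM, n = 9, SD), Osbpl3 (10.7-fold), Pcsk5 (7.96-fold), Fgf11 (7.02-fold), Rap1gap2 (4.34-fold) and the potassium channel gene Kcnf1 (3.45-fold). Cpne6 and Syn2 were higher. In NA, Trib2 was lower, at 0.380 ± 0.258 CPM against 8.81 ± 11.4 CPM in PFC and the levels given above in RSC and VHN (SD, n = 3 each). Rps15 was 4.47-fold lower. Higher in NA were Cdr1, whose locus is transcribed from both strands (3181 ± 615 CPM, n = 3, against 822 ± 335 CPM, n = 9, SD), Tmem47 (2.94-fold), Jcad (2.29-fold), Arhgap32 (1.70-fold) and Prepl. The 45 became 28 and 93 without NA replicates 1 and 3, 16 and 22 without PFC replicates 2 and 3, 22, 21 and 23 without RSC replicates 1, 2 and 3, and 19 and 24 without VHN replicates 2 and 3. DESeq2 called 298.

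Single cells were grouped to ask which cell classes the region holds. The 348 cells formed 8 clusters, 7 of which, with 331 cells, carried pyramidal markers. Cluster 1 held 79 cells (22.7%, exact 95% interval 18.4 to 27.5%). Fstl5 was 21.1-fold over the other cells there (seen in 45.6% of its cells and 3.72% of others), Rprm 6.09-fold and the calcium-binding protein gene S100b 5.83-fold. Teddm3 (5.57-fold), Rasgrp2 (6.54-fold) and Klhl1 (5.94-fold) completed its leading genes. Cluster 2 held 67 cells (19.3%, 15.2 to 23.8%), with the neuropeptide receptor Npbwr1 34.3-fold, Calb1 17.3-fold (91.0% of cells, 17.1% of others) and Kit 7.65-fold higher, besides Nell1, Sstr3 and Grem1. Cluster 3 held 60 cells (17.2%, 13.4 to 21.6%), with Slc35d3 13.6-fold, Gm11730 13.5-fold, the synaptic vesicle gene Sv2c 12.9-fold and Scara3 10.6-fold higher. Cluster 4 held 42 cells (12.1%, 8.84 to 16%), with Kremen2 8.89-fold, the matrix gene Bcan 4.94-fold, Vat1l 4.84-fold and the serotonin receptor Htr1f 4.58-fold higher. Nts was at a mean of 8.75, 10.7 and 6.39 counts per 10000 in clusters 3, 4 and 5 and at most 1.61 in the others. Clusters 3 and 4 were spread unevenly over plates, with 22, 24, 8 and 6 cells and 6, 2, 25 and 9 cells on plates Q5 to Q8. So were cluster 1, with 15, 24, 11 and 29 cells, and the small cluster 8, with 4, 0, 2 and 8.

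Cluster 5 held 38 cells (10.9%, 7.84 to 14.7%), with Gipc2 18.2-fold, Trabd2b 4.19-fold, Sebox 3.66-fold and the glycine receptor Glra3 3.56-fold higher. Cluster 6 held 31 cells (8.91%, 6.13 to 12.4%), with nitric oxide synthase, Nos1, 36.1-fold higher (90.3% of cells, 4.42% of others), besides Fstl4, Foxo1, Gstm7, Tmem255a and BC030499. Wfs1 was seen in 83.9% of its cells and Slc17a6 in none. The CA1 markers as a list were detected in a mean of 58.9% of its cells and 55.3% of others, CA3 and CA2 markers in 33.0% and 19.2%, and dentate markers in 30.4% and 16.1%. Cluster 8 held 14 cells (4.02%, 2.22 to 6.66%) and was marked by Ly6g6e (85.7% of cells, 2.40% of others), Chrm2, Sema5b, Sla2, Pamr1 and Cidea. Cluster 7 held 17 cells (4.89%, 2.87 to 7.71%) that lacked pyramidal markers, which were detected in a mean of 4.81% of its cells and 72.6% of others. Spp1 was seen in 94.1%, Ifitm3 in all and the proliferation gene Mki67 in 76.5% of its cells, and each in 0.302% of others. Tspo (88.2%), Krt18 (76.5%) and the immunoglobulin gene Ighg2b (94.1%) also led it. Marker lists left its type open, since few members were measured (1 of 16 interneuron, 2 of 10 oligodendrocyte precursor, 3 of 12 microglia and 6 of 14 endothelial and mural markers). Endothelial and mural markers were detected in a mean of 31.4% of its cells and 6.14% of others, with Acta2 in 82.4%, and precursor markers in 26.5% and 1.81%. Its median was 36304 counts, and 16 of its 17 wells lay in 1 column per plate. Fn1, Gad1 and Gad2 were not analysed here in single cells.

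The last question was whether genes that differ between populations also vary oppositely from cell to cell. They did for the NA and PFC against RSC and VHN genes, of which 858 and 799 were detected in the 331 pyramidal-like cells. Correlations among genes of 1 side exceeded those between sides by 0.0456, while 0 of 10000 random pairs of matched lists reached that (highest 0.00180). The mean correlation between sides was −0.0176, so opposite variation was weak. The rest of the 0.0456 came from correlation within sides. On single plates the excess was 0.0401 to 0.0506. It was 0.0701 for NA against RSC, 0.0838 for NA against VHN, 0.0607 for PFC against RSC and 0.0913 for PFC against VHN, with highest random values of 0.00353, 0.00459, 0.00235 and 0.00329. The other contrasts had too few genes on a side. A score of these genes per cell averages 0 over these cells by construction. It ranks cells between the 2 sides, and 0 is not a boundary between the populations. Medians lay nearest to 0 in clusters 1, 5 and 8 (0.117, −0.127 and 0.0395). The score was above 0 in 67 of 79 cells of cluster 1, 65 of 67 of cluster 2, 31 of 31 of cluster 6 and 10 of 14 of cluster 8. It was below 0 in 59 of 60 cells of cluster 3, 42 of 42 of cluster 4 and 33 of 38 of cluster 5. The score uses genes that also helped to form the clusters. Without bulk-called genes, 57.0% of cluster 1 and 57.9% of cluster 5 stayed together, and 71.4 to 100% of each other pyramidal cluster. These shares do not tell whether clusters merged. Agreement of that clustering with the main one, as an adjusted Rand index, was 0.542. Calb1 and Kit, higher in NA and PFC, were highest in clusters 2 and 6, and Nts, Trib2 and Gpr101, higher in RSC and VHN, in clusters 3 and 4. Lars2 varied little, from 0.585 to 1.13 counts per 10000 over the 7 pyramidal clusters. The single cells carry no projection label, so no cluster was assigned to a target.

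**Figure D4:**
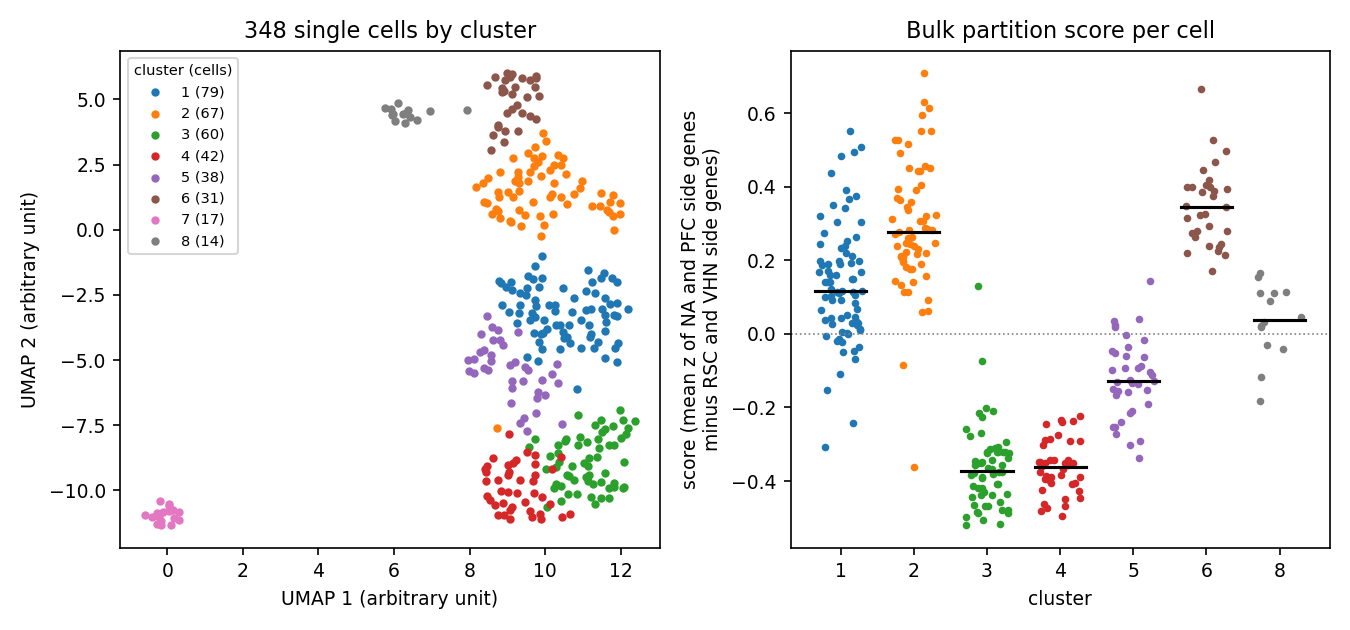
Left, UMAP coordinates (arbitrary units) of 348 single cells coloured by cluster; right, per cell the mean z-score of genes higher in NA and PFC minus that of genes higher in RSC and VHN, by cluster, with a line at the median. Medians were 0.277 and 0.345 in clusters 2 and 6 and −0.371 and −0.363 in clusters 3 and 4.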

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

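Of the alternatives below, 5 were chosen only after the data were seen: NA replicate 2 and PFC replicate 3 left out together, the 3 libraries richest in interneuron transcripts left out, clusters made without bulk-called genes, the wells of 1 column per plate left out, and genes of the lower or upper range of levels alone. Over all alternatives, named genes and called lists, counted together, kept direction and call in 4701 of 5541 tests and lost the call in 838. Of the lost calls, 46 were lists tested with an estimated correlation. Other results stayed the same in 348 of 493 tests. A distance counted as the same when it moved by less than its jackknife error. The RSC and VHN distance therefore counted as the same where it turned from −0.19 to 0.33, without NA replicate 2. The sign of a named gene turned in 2 tests, for Gad1 (3.41) and Gad2 (5.15) without RSC replicates 2 and 3 and VHN replicate 3.

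The tool and the filter moved counts. DESeq2 called 2408 genes among the 4 populations, 464 for NA against PFC, 1654 for NA against RSC, 1077 for NA against VHN, 2128 for PFC against RSC, 1388 for PFC against VHN, 59 for RSC against VHN, 264 for NA and RSC against PFC and VHN, 88 for NA and VHN against PFC and RSC and 298 set apart. It shared 1937 of the 1982 calls of NA and PFC against RSC and VHN, with 0 of opposite sign. Without a low-count filter, in the same order and leaving out PFC against RSC, which stayed within 1.5 times, the counts were 2709, 514, 1353, 904, 1125, 93, 370, 192 and 383. At an adjusted p under 0.01 there were 590 genes among the 4 populations, 10, 321, 116, 595 and 255 for NA against PFC, NA against RSC, NA against VHN, PFC against RSC and PFC against VHN, 976 for NA and PFC against RSC and VHN, 3 and 0 for the other pairings and 6 set apart.

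Libraries mattered as well. Without the 3 libraries richest in interneuron transcripts, which leaves 1 RSC library that is assumed to vary like the others, counts were 446 among the populations, 16, 110, 183, 214 and 298 for the first 5 pairs, 746 for NA and PFC against RSC and VHN, 0 and 0 for the other pairings and 7 set apart. Without NA replicate 2 and PFC replicate 3, the other pairings gave 49 and 6 genes, 17 lists were called, and the distance was 1.40 for PFC and RSC, 1.15 for PFC and VHN and 0.47 for RSC and VHN. With only the 6 libraries compared, NA against PFC gave 0 genes and NA against VHN 171. Leaving out 1 library at a time gave 892 (RSC replicate 2) to 1472 (NA replicate 2) genes among the populations and 1488 (VHN replicate 2) to 2176 (NA replicate 2) for NA and PFC against RSC and VHN. It gave 22 (PFC replicate 2) to 152 (NA replicate 3) for NA against PFC, 387 (RSC replicate 2) to 882 (PFC replicate 3) for NA against RSC, 136 (VHN replicate 1) to 437 (PFC replicate 3) for NA against VHN, 744 (RSC replicate 2) to 1833 (NA replicate 2) for PFC against RSC, 330 (VHN replicate 2) to 1104 (NA replicate 2) for PFC against VHN and 0 to 19 (VHN replicate 1) for RSC against VHN. The other pairings ranged from 2 (RSC replicate 2) to 51 (NA replicate 3) and from 0 to 11 (VHN replicate 1), genes set apart from 16 (PFC replicate 2) to 93 (NA replicate 3) and lists from 32 (PFC replicate 3) to 61 (RSC replicate 1).

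Scaling moved the directions of small shifts. Without normalization, NA against PFC gave 23 genes, NA and RSC against PFC and VHN 5, NA and VHN against PFC and RSC 0, and 17 were set apart. The median of all genes moved by −0.14 for NA against PFC, −0.18 for NA against VHN and −0.12 for NA and RSC against PFC and VHN. Genes of NA against VHN then split into 135 higher and 264 lower, those of NA against RSC into 407 and 405, and those of NA and PFC against RSC and VHN into 913 and 1046, so which side has more genes depends on scaling. RLE size factors moved medians by at most 0.02 and gave 11 genes for NA and RSC against PFC and VHN. With limma on log2(FPKM + 1), the other pairings gave 3 and 0 genes. With log2(FPKM + 0.1) these were 3 and 0, with 37 for NA against PFC and 28 set apart, and 4 of the 1982 genes of NA and PFC against RSC and VHN had the opposite sign.

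Distances between populations depended on the pseudocount. With log2(FPKM + 1) they were 0.67 for NA and RSC, 0.57 for NA and VHN, 0.74 for PFC and RSC and 0.61 for PFC and VHN, and with log2(FPKM + 0.1) 1.08 and 0.89 for the pairs with PFC. Without a low-count filter they were 0.91 for NA and RSC, 1.08 for PFC and RSC and 0.91 for PFC and VHN. PFC and RSC were at 1.23 with a strict filter and 1.15 without the interneuron-rich libraries. With 1 library left out, distances ran from 0.46 (NA replicate 2) to 0.95 (NA replicate 3) for NA and PFC, 0.97 (NA replicate 2) to 1.25 (NA replicate 3) for NA and RSC, 0.73 (NA replicate 2) to 1.17 (NA replicate 3) for NA and VHN, 1.22 (RSC replicate 2) to 1.32 (NA replicate 2) for PFC and RSC, 0.94 (VHN replicate 1) to 1.11 (NA replicate 2) for PFC and VHN and −0.48 (VHN replicate 2) to 0.33 (NA replicate 2) for RSC and VHN.

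The replicate number as a block gave 1098 genes among the populations, 52, 725, 364, 1245, 664 and 0 for the 6 pairs, 1803, 21 and 1 for the pairings and 37 set apart, with 47 lists. Over 18 pairs of libraries with the same number, correlations of their deviations ran from −0.059 to 0.027, and 2 of 12 libraries correlated best with their own number. The numbers were therefore not used as pairs.

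List and marker tests were unstable as well. With an estimated correlation 0 lists were called, against 46 at the preset value and 57 by fry. The adjusted p of oligodendrocyte markers was 0.102 with log2(CPM + 0.1) and 0.0532 with log2(FPKM + 1). With log2(CPM + 10), adjusted p was 0.0377 for astrocyte, 0.0393 for endothelial and mural, 0.0258 for CA3 and CA2 markers and 0.000844 for stress genes.

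Across single cells, segregation was larger by rank correlation, at 0.0823, 0.0962, 0.0715 and 0.104 for the cross pairs (NA against RSC, NA against VHN, PFC against RSC and PFC against VHN) and 0.0541 for NA and PFC against RSC and VHN. With bulk genes at an adjusted p under 0.01 the values were 0.132, 0.181, 0.114, 0.166 and 0.0803. With the lower range of levels they were 0.0503 for NA against RSC, 0.071 for NA against VHN, 0.0734 for PFC against VHN and 0.0406 for NA and PFC against RSC and VHN, which was 0.04 with all cells. Alternative settings gave 6 to 11 clusters, with an adjusted Rand index of 0.542 (clusters made without bulk-called genes) to 0.847. The cause of these changes was not tested. In simulated counts with 3 libraries per population, 22% of genes changed 2-fold were recovered, so small changes can be missed here. Those genes had a mean of at least 10 CPM, and genes under that level were not covered.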

Other observations

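Of the tests below, those of a batch, of interneuron transcripts, of Lars2 in cell classes, of RNA without poly(A) tails and of well positions as controls were chosen only after the result was seen.

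Genes that led the single-cell clusters were also measured in the bulk populations. The 30 leading genes of cluster 3, among them Slc35d3, had a mean level of 5.17 ± 0.0943 in RSC and 4.59 ± 0.535 in VHN, against 1.90 ± 0.166 in NA and 1.67 ± 0.278 in PFC (log2(CPM + 1), SD, n = 3 each; exact permutation F test, adjusted p = 0.00288). Those of cluster 4 were at 4.04 ± 0.0913 in RSC and 3.97 ± 0.292 in VHN, and at 2.27 ± 0.410 in NA and 2.11 ± 0.189 in PFC (adjusted p = 0.00852). Genes of cluster 2, with Calb1 and Kit, were at 4.27 ± 0.381 in PFC, 3.59 ± 0.455 in NA, 2.20 ± 0.778 in VHN and 1.58 ± 0.344 in RSC (adjusted p = 0.00288). Genes of cluster 6, with Nos1, were at 3.93 ± 0.652 in PFC and 2.11 ± 0.371 in NA, against 1.25 ± 0.406 in RSC and 1.35 ± 0.285 in VHN (adjusted p = 0.00288). Genes of cluster 1 were at 4.76 ± 0.193 in NA, 4.53 ± 0.109 in PFC, 3.06 ± 0.205 in RSC and 3.89 ± 0.759 in VHN (adjusted p = 0.00927). For clusters 5 and 8 the adjusted p was 0.0572 and 0.0533. S100b, a leading gene of cluster 1, was at 0.21, 15.1 and 41.3 CPM in VHN replicates 1, 2 and 3.

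The difference of NA and PFC from RSC and VHN may reflect pyramidal cell classes taken in different shares, a hypothesis found and tested on the same data. Leading genes of 5 of 7 clusters differed between the populations. The genes of both sides also segregated within single-cell plates (0.046, highest of 10000 random pairs 0.00186). They still did after quality, depth and stress of each cell were regressed out (0.047, highest of 1000 random pairs 0.00114). A bulk batch that shifted genes unrelated to cell classes is therefore unlikely as the whole cause. A batch that also changed which cell classes were taken would give the same values, so it stays open. A batch as part of the cause stays open too, since a mean over genes does not show how many were shifted. Lars2, treated below, differed more between the sides in bulk than between clusters. Interneuron transcripts as the whole cause are unlikely as well, with 746 genes without the 3 richest libraries, a count reached by 1 of 100 splits of the 9 libraries left, the real one (highest other 672, median of others 0). Dissection position along the subiculum, processing day and animals, which the labels do not give, were not tested and stay open.

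Whether the high Lars2 level of NA and PFC libraries comes from more RNA without poly(A) tails stays open. Without Rpph1, Rmrp, Rn7sk and Gm23583, whose values prompted the test, the mean of 14 small non-coding RNA genes differed by 0.17 (log2(CPM + 1); 0.664 ± 0.258 against 0.494 ± 0.125, SD, n = 6 each; exact permutation test over 924 splits, p = 0.162). Lars2 differed 1.92-fold between clusters (95% interval 1.70 to 4.16) and 8.32-fold in bulk (lower bound 5.64). Even the lowest bulk library, at 884 CPM, lay far above every pyramidal cluster on the same scale. The single-cell counts may therefore not hold the RNA counted as Lars2 in bulk, and cell classes as its source stay open. Stretches of 0 bases in annotated Lars2 transcripts resembled mitochondrial 16S ribosomal RNA, and 0 bases resembled transcripts over nuclear ribosomal DNA. As the reference lacks a 28S sequence, nuclear ribosomal reads stay open.

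Cluster 7 may hold wells loaded by position, such as controls. Of its 17 wells, 94.1% lay in 1 column per plate (column 5 on plate Q5, 6 on Q6, 7 on Q7 and 8 on Q8), in rows A, B, E and F. Random sets of as many passing wells reached at most 29.4% (94.1% against 10000 sets), so cells of another type sorted to random positions are an unlikely source. The other 16 wells of these columns failed the filter, with a median of 88.5 counts, while 332 of 352 wells elsewhere passed. No label describes these wells, so what was loaded stays open.

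Other splits of the 12 libraries were fitted the same way. For the 4-group test, 1 of 100 splits, the real one, gave as many genes (1243, highest other 21), so chance was excluded there. The same held for NA and PFC against RSC and VHN (1982, highest other 166), with 1 of 100. Genes set apart (45, highest other 8) also had 1 of 100. Most other splits mix the 2 sides within groups, which widens the spread. They therefore do not exclude chance for differences between NA and PFC, on which all 45 genes rest. Gene lists had 1 of 100 as well (46, highest other 37, median of others 5). With 0 lists held at an estimated correlation, chance was not excluded for them. For NA and RSC against PFC and VHN (23 genes, highest other 202) and NA and VHN against PFC and RSC (1 gene, highest other 176), 5 of 100 splits each gave as many, so chance was not excluded. Splits with several times the real count there point to a structure of the libraries, which the PC scores also show. Pairs of populations have 10 splits each, too few for a share under 0.05. There 1 of 10 gave as many for NA against PFC (61, highest other 2), NA against RSC (811, highest other 0), NA against VHN (383, highest other 0), PFC against RSC (1358, highest other 0) and PFC against VHN (708, highest other 0), and 10 of 10 for RSC against VHN (0 by edgeR, highest other 10; 721 at an unadjusted p under 0.05, 59 by DESeq2).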
